A study of Homo sapiens with 45 samples.

How the data were processed

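The series holds 45 RNA-seq libraries of the MM.1S multiple myeloma cell line. The deposited table was not analysed here. None of its 45 value columns has a name that matches a label of a sample, so all 45 were left out, and no comparison between compounds, times or DMSO controls was made.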

Results

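RNA-seq was performed on 45 libraries of MM.1S, an established human multiple myeloma cell line. By their titles, the libraries form 15 groups of 3. Each of 5 compounds has a DMSO group at 0 h and treated groups at 6 h and 24 h. The compounds were KB528, directed at the catalytic domain of p300, at 0.5 uM, the p300 bromodomain inhibitors GNE-781 at 0.3 uM and CCS-1477 at 3 uM, the BET inhibitor JQ1 at 0.5 uM, and lenalidomide at 1 uM. No DMSO group at 6 h or 24 h is listed. A treated group set against its 0 h DMSO group would therefore not separate treatment from time in culture.

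Expression values are not reported here. The deposited table has 45 value columns, and the name of 0 of them matched a label of a library. No column was therefore assigned to a compound, a time or a DMSO control, and no comparison between groups was made.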

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

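No test of expression was run, since none of the 45 value columns was assigned to a library. Column names were matched to labels as whole words, which gave 0 matches. This whole-word rule was not planned in advance either. An alternative chosen after seeing the data, which accepts a name anywhere inside a label, gave 2. Both of these name parts were found only within the compound name CCS1477 and name no library, so neither column was used. No paired analysis was possible because the columns carry no replicate numbers that match the labels.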
